A study of Mus musculus with 5 samples.

How the data were processed

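Poly(A)-selected RNA was sequenced from lung endothelial cells of mice that had received angiotensin II, a vasoconstrictor peptide hormone, by infusion for 28 days. Per the labels' protocols, reads were paired-end, 150 bp long and from an Illumina NovaSeq instrument. The labels gave 3 libraries from wild-type (WT) mice and 2 from mice that lacked TET2 in endothelial cells (TET2KO). TET2 is a dioxygenase that oxidises 5-methylcytosine in DNA. The labels did not say how endothelial cells were isolated, which exons of Tet2 were deleted, or whether each library came from a separate animal, so p-values measured the spread between these libraries, part of which may be technical.

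Per the submitters' processing notes, the authors used Trimmomatic 0.36, STAR 2.5.2b, featureCounts of Subread 1.5.2 and DESeq2 (version not given), with the mouse genome build GRCm38. The strand setting of the counting was not given in the sources used here, so reads of genes that overlap on opposite strands could not be told apart. The authors deposited whole-number read counts per gene for 49315 Ensembl gene identifiers, of which 174 carried no symbol. The authors also deposited TPM values, which were counts scaled by gene length and library total. Their comparison table, per the file headers, held log2 fold changes, p-values and adjusted p-values for 18019 genes, together with counts divided by a size factor for each library, a normalized signal. Every gene in that table had at least 51 counts summed over the libraries, and no gene outside it had more than 50. A shorter deposited table held the 217 genes with an adjusted p-value under 0.05 and an absolute log2 fold change over 1.

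Total counts per library ranged from 27346804 to 35440257. Counting error was small at that depth for highly expressed genes, but not for those with few counts, such as Rian (19 to 23 counts per WT library), Gucy1a1 (38 to 57) and Muc16 (47 to 76). The biological coefficient of variation estimated by edgeR was 0.339.

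Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, genotype as the only term, low counts removed by filterByExpr) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over the 18727 genes tested. Adjusted p under 0.05 was the threshold. Each gene's standard error was its log2 fold change divided by the square root of its F statistic. CPM values used TMM-scaled library totals unless stated otherwise, and log2 CPM used a prior count of 2. Fold changes are TET2KO relative to WT.

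Gene lists for lung endothelium, angiotensin II, DNA demethylation and the other cell types that a lung isolate could hold were written before the data were examined. Of the 54 lists, 53 had at least 5 tested members. They were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists by Benjamini-Hochberg. Camera with an estimated correlation and fry, in its directional and mixed forms, were run beside it. The lists overlapped in part, so their results were not independent.

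The genes named in the text followed a rule written before the data were examined. It took Tet1, Tet2 and Tet3. It took the 12 genes with the largest rise and the 12 with the largest fall among genes past the adjusted threshold, of which there were none. It took up to 4 members with the smallest p from each list called by camera, from every list of another cell type, and from the lists for endothelial identity, angiotensin and vasoactive genes, endothelial to mesenchymal transition and leukocyte adhesion. Because fewer than 10 genes passed, it also took the 20 genes with the smallest p and a mean log2 CPM of at least 1. The rule took more genes than are printed, and those printed from it are a selection made after their values were seen. Genes named outside this rule are said to have been chosen after their values were seen.

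Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom and the legacy spread of edgeR, RLE, upper quartile and no scaling factors, no filter or at least 1 CPM in 2 libraries, each library left out in turn, the replicate number as a block, and limma on log2(TPM + 1) or log2(TPM + 0.1). Scaling on the endothelial identity list was added after the data were seen. The deposited comparison was checked by running DESeq2 on the deposited counts for every split of the 5 libraries into 3 and 2.

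The tests were checked on counts simulated for the TET2KO against WT comparison from the means, dispersions and library sizes of the real libraries, with 100 genes changed 2-fold and 100 changed 4-fold among 18254 genes. edgeR recovered 3% of the 2-fold and 56% of the 4-fold changes with 6 false calls. DESeq2 recovered 20% and 88% with 74 false calls. In a further simulation with 18727 genes in which only the endothelial identity list was shifted, by 0.75 on the log2 scale, the adjusted p of that list by camera was 9.4e-16 at the preset correlation and 0.298 with an estimated correlation. Genes were simulated independently of each other, so the simulation did not test how often camera at the preset correlation calls an unshifted list whose genes vary together.

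Gene positions were taken from GENCODE release M21 on GRCm38, in which 49056 of the 49315 identifiers were found, 48795 of them with the same symbol. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.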

Results

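RNA levels were measured by poly(A) RNA-seq in lung endothelial cell isolates from WT mice and from mice with an endothelial-specific knockout of TET2, all infused with angiotensin II for 28 days. The comparison asked how the loss of TET2 in endothelial cells changed their transcripts under this hormone. There were 3 WT and 2 TET2KO libraries. Total counts were 27346804, 35440257 and 31005444 in WT replicates 1 to 3, and 31239463 and 30035235 in TET2KO replicates 1 and 2. Of 49315 genes in the count table, 30203 had any count and 18727 were tested.

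The libraries held transcripts of several lung cell types besides endothelium. Pecam1 and Cdh5, endothelial adhesion genes, were counted in every library, and so were the leukocyte genes Ptprc, Cd74 and Ighm. Before TMM scaling, Cdh5 was at 656, 404 and 966 CPM in the WT libraries and at 1331 and 1237 CPM in the TET2KO libraries. Ptprc, the pan-leukocyte antigen CD45, was at 1578, 1006 and 1419 CPM in WT and at 1277 and 1237 CPM in TET2KO. Lyz2, the lysozyme of myeloid cells, was at 15213 CPM in WT replicate 2 and between 1788 and 5488 CPM in the other 4 libraries. These 6 genes were chosen after their values were seen. WT replicate 2 stood apart from the rest: the first principal component held 57.5% of the variance and placed it at 90.8, with the other 4 libraries between -50.9 and 7.71. Across genes, which are not independent replicates, Pearson correlations of log2 CPM were 0.944 to 0.968 between WT replicate 2 and the other libraries and 0.971 to 0.987 among the others. No pair of libraries agreed within counting noise.

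Tet2, the targeted gene (ENSMUSG00000040943, chromosome 3, 133463679 to 133545139, minus strand, GRCm38), did not differ between the groups over the whole gene. Its raw counts were 4018, 5142 and 4130 in the WT libraries and 4608 and 5188 in the TET2KO libraries. Tet2 stood at 149 ± 22.3 CPM in WT (SD, n = 3) and 151 ± 16.5 CPM in TET2KO (SD, n = 2). Its log2 fold change was 0.02 (SE 0.19), with an adjusted p of 0.987 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A count over the whole gene does not check the genotype labels here, since the deleted exons were not in the labels and leukocytes in the isolate also express Tet2. Tet3, another enzyme of the family, had a log2 fold change of 0.07 (SE 0.19). Tet1, the remaining member, was at 6.47 ± 0.269 CPM in WT (SD, n = 3) and 10.6 ± 2.16 CPM in TET2KO (SD, n = 2), a log2 fold change of 0.71 (SE 0.22) that failed the correction (edgeR adjusted p = 0.759).

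The genes with the strongest evidence of a difference were all higher in the TET2KO libraries. Hspa12b, a heat shock protein family member of endothelium, was at 56.7 ± 5.73 CPM in WT and 128 ± 5.95 CPM in TET2KO (SD, n = 3 and 2), a log2 fold change of 1.17 (SE 0.16). Prickle1, of the planar cell polarity pathway, differed by 1.45 (SE 0.20) on the log2 scale, from 54.8 ± 3.10 to 149 ± 39.5 CPM. Hey1, a Notch target transcription factor, was at 38.2 ± 5.74 CPM in WT and 80.8 ± 2.07 CPM in TET2KO. Fendrr, a long non-coding RNA beside Foxf1, was at 241 ± 34.9 and 524 ± 43.0 CPM. Jcad, an endothelial junction gene, was at 105 ± 14.6 and 215 ± 2.62 CPM. None of these passed the correction: edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes, with a lowest adjusted p of 0.740.

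All 20 genes with the smallest p were higher in TET2KO, with log2 fold changes between 0.86 and 2.02, and in each of them both TET2KO libraries lay above all 3 WT libraries. Picking genes by p favours groups that do not overlap, so the lack of overlap is no separate evidence. Besides those above the 20 genes were Mapt, Myzap, Phldb1, Efna1, Kank3, Casz1, Rasgef1a, Card10, Rgs12, Pde9a, Glis2, Stard8, Msln, Plod2 and Slc9a3r2. Msln, the mesothelial surface protein mesothelin, had the largest of these fold changes, from 2.19 ± 0.335 CPM in WT to 8.87 ± 3.75 CPM in TET2KO (SD, n = 3 and 2). Casz1, a zinc finger transcription factor of vascular development, was at 133 ± 7.42 and 253 ± 3.19 CPM. Efna1, the ligand ephrin-A1, was at 23.3 ± 2.26 and 50.9 ± 6.78 CPM. Hspa12b lies on chromosome 2 (131127280 to 131146321, plus strand) and Prickle1 on chromosome 15 (93499114 to 93595891, minus strand). Of the 20 genes, 9 overlap an annotated gene on the opposite strand, Fendrr (chromosome 8, 121054882 to 121083110, minus strand) among them.

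At an unadjusted p under 0.05, edgeR counted 1098 genes against 936 given by chance, 997 of them higher and 101 lower in TET2KO. By limma-voom the count was 1109, with 0 past the adjusted threshold. The spread of such counts is wide when genes vary together: other splits of the 5 libraries into 3 and 2 gave edgeR counts from 118 to 3463. The edgeR count was 283 without TET2KO replicate 2, 693 without TET2KO replicate 1, 725 without WT replicate 1 and 1876 without WT replicate 2. Without WT replicate 3 the edgeR count was 1407. DESeq2 called 60 genes at an adjusted p under 0.05, all higher in TET2KO, 43 of them with an absolute log2 fold change over 1. In all 60 the groups did not overlap, which picking genes by p favours, and all 20 genes above were among them. Of the 10 splits of the 5 libraries into 3 and 2, 4 gave as many DESeq2 calls, the real split included, with a highest other count of 1080. On the simulated counts DESeq2 made 74 false calls, so these 60 calls do not establish an effect of genotype. Over all tested genes, both TET2KO libraries lay above all WT libraries for 12.4% of genes and below them for 12.4%, where chance gives 10% per direction.

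**Figure D1:**
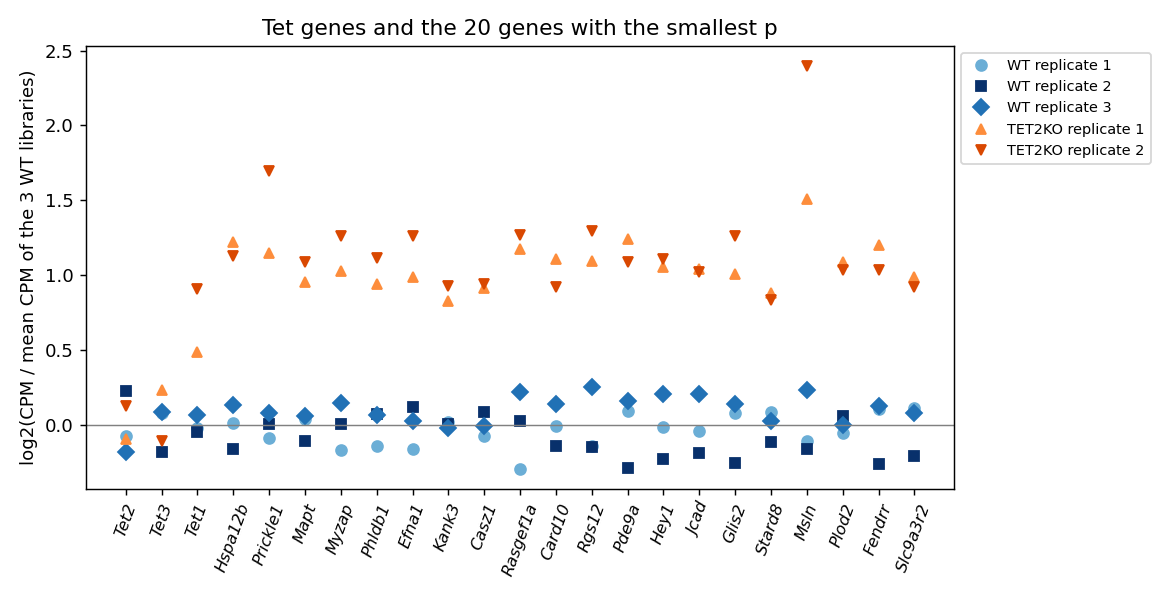
Each point is the log2 ratio of a library's CPM (TMM scaled) to the mean CPM of the 3 WT libraries, for Tet1, Tet2, Tet3 and the 20 genes with the smallest p. Circles, squares and diamonds are WT libraries and triangles are TET2KO libraries. For Tet2 the groups overlap, while for each of the 20 genes both TET2KO libraries lie above all 3 WT libraries, and none of these genes passed the adjusted threshold of edgeR. The 20 genes were picked by p, which favours groups that do not overlap.

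Genes that mark endothelial cells were higher in the TET2KO libraries as a group. Of the 30 members of the endothelial identity list, 29 had a log2 fold change above 0, and for 28 both TET2KO libraries lay above all 3 WT libraries. The list's median log2 fold change was 0.75, and camera called it higher (adjusted p = 3.9e-17 at the preset correlation). With an estimated correlation the adjusted p was 0.333. Sox18, a transcription factor of vascular development, was at 51.3 ± 0.421 CPM in WT and 105 ± 29.2 CPM in TET2KO (SD, n = 3 and 2). Egfl7, a secreted endothelial factor, was at 249 ± 18.9 and 414 ± 9.83 CPM. The log2 fold change was 0.88 (SE 0.22) for Erg, an endothelial transcription factor, and 0.82 (SE 0.21) for Ramp2, the partner of the adrenomedullin receptor. No member passed the correction over all genes, and 10 passed when adjusted over the list alone. The list held 0.673%, 0.481% and 0.892% of counts in WT replicates 1 to 3, and 1.19% and 1.27% in TET2KO replicates 1 and 2.

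Lists for the vessel types of the lung were called higher too. With an estimated correlation the adjusted p was 0.333 for each but the venous list, where it was 0.411. The medians were 0.72 for general capillary genes, 0.72 for aerocytes, the capillary cells of gas exchange, and 0.78 for arterial endothelium. They were 0.52 for venous and 0.41 for lymphatic endothelium. Kit, the stem cell factor receptor carried by general capillary cells, was at 139 ± 30.4 CPM in WT and 273 ± 42.4 CPM in TET2KO (SD, n = 3 and 2). Dll4, an arterial Notch ligand, was at 85.4 ± 19.96 and 151 ± 6.98 CPM, and Gja4, the arterial connexin 37, at 20.9 ± 7.54 and 45.6 ± 3.63 CPM. Lyve1, a hyaluronan receptor of lymphatic vessels, was at 172 ± 22.2 and 306 ± 16.0 CPM. Adjusted over the list alone, 2 aerocyte, 5 arterial and 1 lymphatic member passed, with 0 in the general capillary and venous lists. The venous call was lost without TET2KO replicate 2, where the median was 0.04, and the lymphatic median was 0.19 without it and 0.61 on log2(TPM + 1). Without WT replicate 2, where macrophage transcripts were highest, the endothelial identity median was 0.63.

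Genes of vascular tone and matrix followed the same direction. In the list of angiotensin and vasoactive genes, 25 of 30 members were above 0 and the median was 0.76. Npr1, the receptor of atrial natriuretic peptide, was at 104 ± 22.8 CPM in WT and 185 ± 6.65 CPM in TET2KO (SD, n = 3 and 2). Nos3, the endothelial nitric oxide synthase, was at 22.1 ± 3.25 and 38.7 ± 7.49 CPM, and Gucy1a1, a subunit of the nitric oxide receptor, at 1.69 ± 0.356 and 4.28 ± 0.739 CPM. In the list for extracellular matrix and fibrosis, 38 of 40 members were above 0, with a median of 0.68. Eln, which encodes elastin, was at 102 ± 19.4 and 252 ± 103 CPM, and Sparc, a matrix-binding glycoprotein, at 76.5 ± 13.3 and 142 ± 15.4 CPM. The list for endothelial to mesenchymal transition had a median of 0.38, with 22 of 27 members above 0. Mmp14, a membrane-bound collagenase, was at 12.3 ± 1.37 and 20.1 ± 2.56 CPM. Camera called these 3 lists higher at the preset correlation, and with an estimated correlation each had an adjusted p of 0.333. Adjusted over the list alone, 0 members passed in each. The median of the transition list was 0.70 without WT replicate 1 and 0.57 on log2(TPM + 1). Lists of matrix-producing cells had medians above 0 in the same comparison: 1.64 for mesothelium, 0.50 for pericytes and smooth muscle and 0.38 for fibroblasts.

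Signalling lists were called higher too. With an estimated correlation the adjusted p was 0.354 for flow-responsive genes and 0.333 for the others. The medians were 0.63 for angiogenesis and the VEGF pathway, 0.48 for the Wnt pathway, 0.45 for the Notch pathway, 0.39 for flow-responsive genes and 0.18 for TGF-beta and BMP targets. Notch4, an endothelial Notch receptor, was at 134 ± 33.4 CPM in WT and 255 ± 32.3 CPM in TET2KO (SD, n = 3 and 2). Lrp5, a Wnt co-receptor, was at 89.8 ± 7.17 and 153 ± 4.62 CPM. Id1, a target of BMP signalling, was at 54.4 ± 1.91 and 94.5 ± 15.7 CPM, and Cav1, the main protein of caveolae, at 347 ± 50.9 and 517 ± 52.6 CPM. Adjusted over the list alone, 1, 3, 1, 0 and 2 members passed in these lists. The TGF-beta and BMP median was 0.35 without WT replicate 2, 0.58 without WT replicate 3, 0.12 without TET2KO replicate 1 and 0.28 without TET2KO replicate 2, and it was 0.29 with library totals and 0.36 on log2(TPM + 1). The Wnt median was 0.29 without TET2KO replicate 1 and the flow median 0.59 without WT replicate 3. The endothelial identity list shares 4 members with the angiogenesis list, 3 with the vasoactive list, 3 with the flow list and 1 with the TGF-beta and BMP list. Other lists share members too. Hey1 is in the arterial, Notch and TGF-beta and BMP lists, Dll4 in the arterial, Notch and angiogenesis lists, and Nkd1 in the aerocyte and Wnt lists. Hey1 and Nkd1 passed in each of their lists when adjusted over the list alone, so the members that passed are in part the same genes. In the same comparison the medians of cell type lists were 0.75 for endothelial identity, 1.64 for mesothelium and 1.04 for alveolar type 1 cells.

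Among inflammation and haemostasis lists, interferon-stimulated genes, complement, leukocyte adhesion and coagulation were called higher. With an estimated correlation their adjusted p values were 0.333, 0.411, 0.376 and 0.333. Interferon-stimulated genes had a median of 0.31, with 37 of 45 members above 0, and complement genes a median of 0.53, with 14 of 20. Leukocyte adhesion and chemokine genes had a median of 0.42, with 19 of 24, and coagulation and fibrinolysis genes a median of 0.14, with 15 of 25. Adjusted over the list alone, 0 members passed in any of them. Oasl2, induced by interferon, was at 22.7 ± 6.90 CPM in WT and 43.6 ± 4.36 CPM in TET2KO (SD, n = 3 and 2), and the chemokine Ccl2 was at 10.8 ± 1.95 and 18.1 ± 4.47 CPM. F13a1, the A subunit of coagulation factor XIII, was at 21.4 ± 1.84 and 46.6 ± 15.6 CPM, while Plaur, the urokinase receptor, was at 554 ± 113 and 379 ± 29.4 CPM. The adhesion median was 0.02 without TET2KO replicate 2, which ended that call, 0.24 and 0.68 without WT replicates 1 and 2, and 0.64 without TET2KO replicate 1. The complement call was lost without WT replicate 3 (median 0.50), and the median was 0.32 without TET2KO replicate 2. The coagulation call was lost without WT replicate 3 (0.35) or TET2KO replicate 2 (0.18), and its median was 0.27, 0.45 and 0.26 without WT replicate 1, WT replicate 2 and TET2KO replicate 1. The interferon median was 0.17 without TET2KO replicate 1. On log2(TPM + 1) the interferon, adhesion and coagulation medians were 0.53, 0.67 and 0.43, and with library totals the coagulation median was 0.26, with the coagulation call lost in both.

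Lists for several other cell types also had medians above 0, though the groups overlapped for some of them. Against the mean of the 5 libraries, alveolar type 2 genes lay at 0.70 in WT replicate 1 and 0.24 in TET2KO replicate 1. Platelets lay at 1.10 in WT replicate 1 and at 0.70 and -0.01 in TET2KO. Fibroblasts lay at 0.29 in WT replicate 1 and 0.24 in TET2KO replicate 1. Airway epithelium lay at 0.10 in WT replicate 2 and -0.09 in TET2KO replicate 1. Mesothelium had the largest median of all lists, 1.64, with 9 of 10 members above 0 and 8 past the threshold adjusted over the list alone. Its share of counts was 0.0196%, 0.0376% and 0.0082% in WT replicates 1 to 3, and 0.0122% and 0.0315% in TET2KO replicates 1 and 2. The pan-epithelium share was 0.0220%, 0.0456% and 0.0090%, and 0.0136% and 0.0350%, in the same order. Both shares were highest in WT replicate 2, while that of alveolar type 1 cells was highest in TET2KO (0.0906% and 0.102%). The medians were 1.04 for alveolar type 1 cells, 0.75 for alveolar type 2 cells, 1.01 for airway epithelium and 1.06 for pan-epithelium. They were 0.38 for fibroblasts, 0.50 for pericytes and smooth muscle, 0.54 for cardiomyocytes and 0.35 for platelets. Muc16, a mesothelial mucin, was at 2.07 ± 0.545 CPM in WT and 6.96 ± 1.98 CPM in TET2KO (SD, n = 3 and 2). Ager, the alveolar type 1 receptor RAGE, was at 19.96 ± 1.94 and 42.6 ± 18.7 CPM, and Sftpb, the surfactant protein B of alveolar type 2 cells, at 76.7 ± 52.8 and 133 ± 40.4 CPM. Bpifb1, a secretory airway gene, was at 5.19 ± 0.544 and 12.996 ± 3.81 CPM, and Limch1 of the fibroblast list at 18.05 ± 6.11 and 36.3 ± 5.30 CPM. Adjusted over the list alone, 9 alveolar type 1, 1 airway and 1 pan-epithelial member passed, and 0 in the other 5 lists. Camera called these 9 lists higher, and with an estimated correlation the adjusted p ran from 0.333 to 0.584. The airway and pan-epithelium calls were lost without TET2KO replicate 2, where their medians were 0.26 and 0.44, and the airway median was 1.61 without TET2KO replicate 1. The platelet call was lost without WT replicate 2 (median 0.03), WT replicate 3 (0.08) or TET2KO replicate 1 (-0.15), and its median was 1.39 without WT replicate 1 and 0.71 without TET2KO replicate 2. The alveolar type 2 median was 1.496 without WT replicate 1, 0.41 without WT replicate 3 and 0.37 without TET2KO replicate 2. The fibroblast median was 0.84 without WT replicate 1 and 0.20 without WT replicate 3.

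Leukocyte lists were not called with all 5 libraries, TMM scaling and the low-count filter. The medians were -0.62 for macrophages and monocytes, 0.22 for neutrophils, 0.00 for T and NK cells and -0.29 for B and plasma cells. In the T and NK list the mean was below 0 and the test pointed up. Macrophage and monocyte members took 3.54% of counts in WT replicate 2 and between 0.406% and 1.15% in the other libraries, and without WT replicate 2 their median was 0.18. C1qa, a complement gene of tissue macrophages, was at 15.2 ± 5.69 CPM in WT and 29.7 ± 6.02 CPM in TET2KO (SD, n = 3 and 2), while Trem2, a lipid receptor of macrophages, was at 53.7 ± 71.5 and 10.05 ± 5.15 CPM. Cd2, an adhesion receptor of T cells, was at 228 ± 10.1 and 158 ± 10.7 CPM. Leaving out a library gave calls in all 4 lists. Without WT replicate 2, T and NK cells (median -0.24) and B and plasma cells (-0.65) were called lower. Macrophages and monocytes were called lower without WT replicate 3 (-0.99) or TET2KO replicate 2 (-1.40), and neutrophils higher without TET2KO replicate 2 (0.36). The neutrophil median was 0.69 without WT replicate 2 and 0.04 without TET2KO replicate 1. With all 5 libraries and no filter on low counts, camera at the preset correlation called neutrophils higher, with a median of 0.78 (adjusted p = 0.020), while with at least 1 CPM in 2 libraries the neutrophil median was -0.28.

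**Figure D2:**
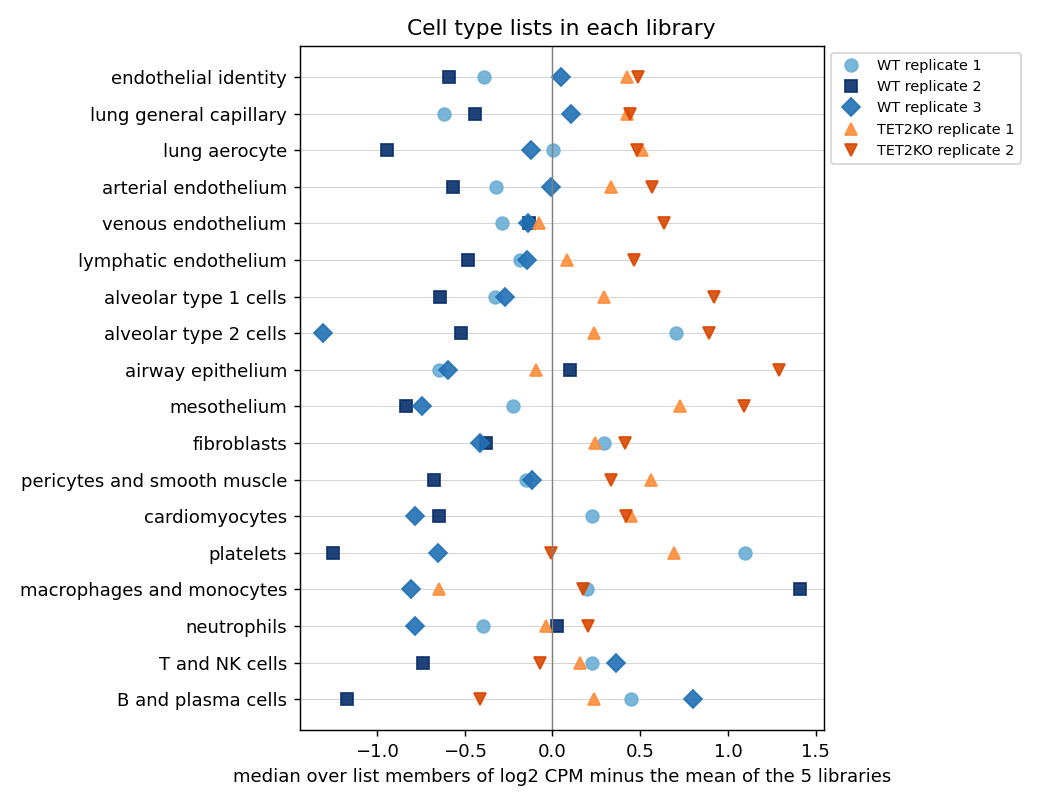
Each point is the median over the members of a cell type list of a library's log2 CPM minus the mean of the 5 libraries. The endothelial identity list lies at 0.42 and 0.49 in the TET2KO libraries and at -0.39, -0.59 and 0.05 in WT replicates 1 to 3, while the macrophage and monocyte list lies at 1.41 in WT replicate 2 and at 0.20 or below in the other libraries.

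Lists of housekeeping, metabolic, S phase and red blood cell genes were the 5 called lower. With an estimated correlation the adjusted p ran from 0.556 to 0.729. All 40 ribosomal protein genes had a log2 fold change below 0, with a median of -0.33, and all 37 nuclear genes of oxidative phosphorylation did, with a median of -0.36. Members of a list varied together (estimated correlations 0.899 and 0.917), so their signs were not independent. Both TET2KO libraries lay below all WT libraries for 13 and 23 of these genes, against 12.4% of all genes. Against the mean of the 5 libraries, the ribosomal list lay at -0.16 in WT replicate 2 and at -0.12 and -0.27 in TET2KO. The medians were -0.29 for S phase, though 0.01 on log2(TPM + 1), -0.35 for fatty acid and cholesterol metabolism and -0.47 for red blood cells. Rps2, a protein of the small ribosomal subunit, was at 672 ± 24.3 CPM in WT and 502 ± 11.1 CPM in TET2KO (SD, n = 3 and 2). Ndufs3, a complex I subunit, was at 36.3 ± 3.39 and 28.7 ± 0.570 CPM, and the haemoglobin gene Hbb-bs at 37.3 ± 4.46 and 27.01 ± 3.11 CPM. Adjusted over the list alone, 0 members passed in these 5 lists. Without WT replicate 2 the S phase and fatty acid medians were 0.11 and 0.14, neither called, and the oxidative phosphorylation median was -0.11. The fatty acid call was also lost without TET2KO replicate 1, the S phase call without TET2KO replicate 2, and the red blood cell call without WT replicate 1 (median -0.23) or TET2KO replicate 2. The ribosomal protein median was -0.15 without WT replicate 3. The median of all genes was -0.08 with TMM factors, 0.06 with library totals and 0.13 on log2(TPM + 1). In that order of settings, the ribosomal protein median was -0.33, -0.21 and -0.10, and relative to all genes -0.26, -0.27 and -0.23. The oxidative phosphorylation median was -0.36, -0.19 and -0.12, and relative to all genes -0.28, -0.26 and -0.25. The fatty acid median was -0.35, -0.17 and -0.05, and relative to all genes -0.28, -0.23 and -0.18. The S phase median was -0.29, -0.13 and 0.01, and relative to all genes -0.21, -0.20 and -0.12. The red blood cell median was -0.23 on log2(TPM + 1).

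Imprinted genes, which are expressed according to parental origin, had a median of 0.56 with 14 of 19 tested members above 0. Camera called the list higher, the adjusted p with an estimated correlation was 0.333, and 4 members passed when adjusted over the list alone. Grb10, an imprinted growth inhibitor, was at 15.9 ± 2.11 CPM in WT and 29.6 ± 1.09 CPM in TET2KO (SD, n = 3 and 2). Peg3, a zinc finger gene expressed from the paternal allele, was at 8.41 ± 1.89 and 16.4 ± 0.951 CPM, and Rian, a long non-coding RNA that overlaps 19 annotated small or short genes, at 0.695 ± 0.102 and 2.02 ± 0.465 CPM. The median was 0.31 without WT replicate 2 and 0.31 without TET2KO replicate 2. Cell type lists had medians above 0 in the same comparison: 1.64 for mesothelium, 0.75 for endothelial identity, 0.50 for pericytes and smooth muscle and 0.38 for fibroblasts. The list of DNA methylation and demethylation enzymes was not called, with a median of -0.13, nor were germline genes repressed by DNA methylation, with a median of -0.05 over 6 tested members of 18 listed. Without a filter on low counts the germline median was -0.54, and the list was not called (camera adjusted p = 0.073).

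In all, camera called 28 of 53 lists higher and 5 lower at the preset correlation, and 0 with an estimated correlation (lowest adjusted p = 0.333). In the simulation, camera with an estimated correlation gave a list shifted by 0.75 an adjusted p of 0.298. The lack of calls by that form therefore does not show that the lists were unshifted. The preset correlation between genes was 0.01, against estimates of 0.568 for endothelial identity, 0.899 for ribosomal proteins and 0.917 for nuclear genes of oxidative phosphorylation. By fry, 0 lists passed, with a lowest adjusted p of 0.187 in the directional and 0.143 in the mixed test. Not called besides those above were class I and class II antigen presentation, with medians of -0.13 and -0.32, NF-kappaB targets at -0.12, inflammasome genes at -0.23, oxidative stress at -0.46 and glycolysis at -0.32. The same held for mitochondrially encoded genes at -0.15, hypoxia targets at -0.04, G2 and M phase at -0.24, p53 targets at -0.17, senescence genes at -0.09, the unfolded protein response at -0.18, heat shock at -0.03 and immediate early genes at 0.03. Median, mean and test differed in sign for NF-kappaB targets, hypoxia targets, senescence genes and heat shock. Without WT replicate 2, senescence genes (median 0.61), G2 and M phase (0.38) and immediate early genes (0.23) were called higher. G2 and M phase was called lower without WT replicate 3 (-0.47) or TET2KO replicate 2 (-0.45). Oxidative stress was called lower without WT replicate 1 (-0.53), WT replicate 3 (-0.71) or TET2KO replicate 2 (-0.54), and glycolysis without WT replicate 1 (-0.38) or TET2KO replicate 2 (-0.38). With all libraries, oxidative stress was called lower with upper quartile scaling (-0.35), library totals (-0.28), no filter (-0.42) and on log2(TPM + 1) (-0.12). On log2(TPM + 1), glycolysis was called lower (-0.09) and immediate early genes higher (0.33). Class II antigen presentation was called lower without WT replicate 2 (-0.60) or TET2KO replicate 1 (-0.62).

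The authors' deposited table listed 299 genes at an adjusted p under 0.05, 217 of them with an absolute log2 fold change over 1, of which 122 were higher and 95 lower. DESeq2 on the deposited counts gave the log2 fold changes of the authors' deposited table to within 4.0e-05 for all 18019 genes when WT replicate 3 was placed with the 2 TET2KO libraries against WT replicates 1 and 2. With the groups of the labels, the largest difference from the authors' deposited table was 5.03, Pearson's r across genes was 0.806, and DESeq2 called 67 of its genes, 2 of which were among the 299. The sample labels name WT replicate 3 as wild type, and all other comparisons here use the labels.

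In the authors' deposited table, Bcar1, an adaptor protein of focal adhesions, was listed with a log2 fold change of 1.86, against 0.65 by the labels (edgeR adjusted p = 0.868). Pde3a, a cyclic nucleotide phosphodiesterase, was listed at 1.37 in the authors' deposited table, against 0.98 by the labels (edgeR adjusted p = 0.842). Trem2 was listed at -3.19 in the authors' deposited table, against -2.42 by the labels (edgeR adjusted p = 0.864). All 95 genes listed lower in the authors' deposited table had their highest normalized count in WT replicate 2, where 35.2% of all its genes did. Of its 122 higher genes 49, and of its 95 lower genes 0, reached an unadjusted p under 0.05 by edgeR with the groups of the labels. All 217 had the same sign under both groupings, as did 76.4% of all 17981 genes compared, and the groupings place 4 of the 5 libraries alike. Bcar1 and Pde3a had the smallest p-values in the authors' deposited table among its higher genes, and were chosen after their values were seen.

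**Figure D3:**
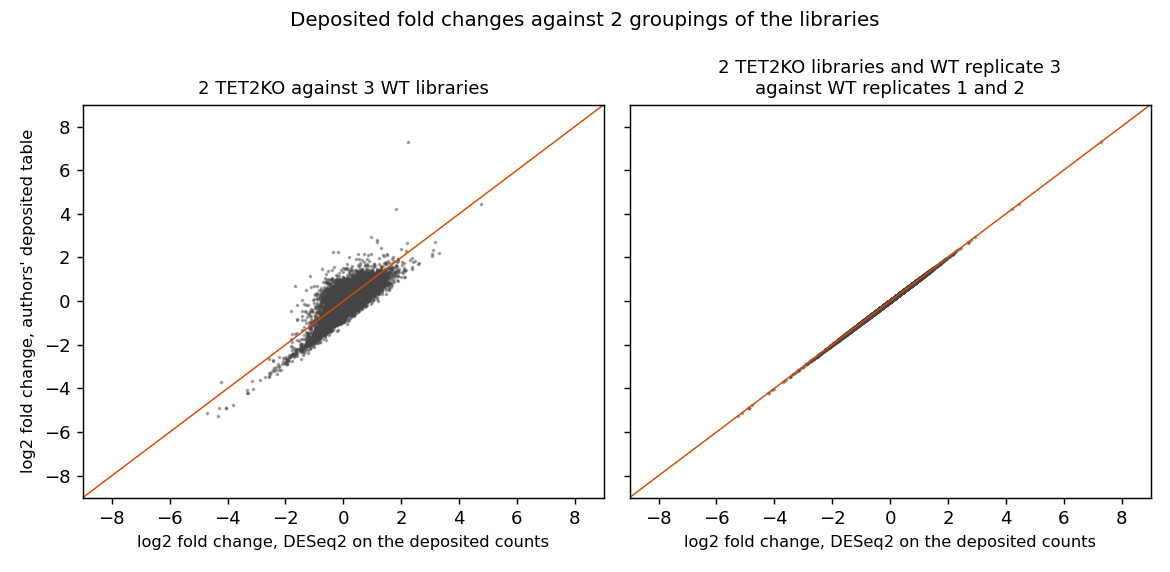
Each point is 1 of the 18019 genes of the authors' deposited table, with its deposited log2 fold change on the vertical axis and that of DESeq2 on the deposited counts on the horizontal axis, for the groups of the labels (left) and with WT replicate 3 placed among the TET2KO libraries (right). The line marks equal values, from which the right-hand points depart by at most 4.0e-05 and the left-hand points by up to 5.03.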

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

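Of the settings below, only the scaling on the endothelial identity list and the count over other splits of the libraries were chosen after the results were seen.

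By edgeR, 0 genes passed under every normalization, filter and left-out library, with the replicate block and with the endothelial scaling, and limma-voom and limma on TPM values also called 0. DESeq2 called 60, of which 60 were higher, and 23 of the 66 genes followed through the settings besides Tet2 were among them. Other splits of the 5 libraries into 3 and 2 gave as many DESeq2 calls in 4 of 10 cases, the real split included, with a highest other value of 1080 (WT replicate 2 and TET2KO replicate 2 against the rest). With 10 splits no share under 0.05 can be reached, and the 1080 calls, several times the real count, point to a structure of the samples. That split sets the libraries with replicate number 2 against the others, and the labels do not say what the number marks. Where a TET2KO library was left out, the remaining one was assumed to vary like the WT libraries. At this depth and number of libraries the self-test with edgeR missed most 2-fold changes.

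Camera at the preset correlation called 28 lists higher and 5 lower. With an estimated correlation 0 were called higher and 0 lower, with fry 0 and 0, and with mixed fry 0 and 0. In the simulation, camera with an estimated correlation did not call the shifted list either (adjusted p = 0.298). The cause of the lost calls was not tested. The preset correlation lay far below most estimates, such as 0.568 for endothelial identity and 0.899 for ribosomal proteins. The coagulation call was lost too, though its estimate was 0.0043. Lists called lower numbered 5 to 8 over the left-out libraries. The RLE factors and the absence of a filter kept all 33 calls, while upper quartile scaling ended the coagulation call, library totals and TPM the coagulation and platelet calls, and the stricter filter the fatty acid call. Oxidative stress was called lower with upper quartile scaling (-0.35), library totals (-0.28), no filter (-0.42), the replicate block (-0.61) and TPM (-0.12). Other calls gained were neutrophils higher without a filter (0.78), and on TPM glycolysis lower (-0.09) and immediate early genes higher (0.33). With the replicate block they were glycolysis (-0.40), G2 and M phase (-0.39) and macrophages and monocytes (-1.09) lower, and T and NK cells (0.32) and B and plasma cells (0.27) higher. With the replicate block, 8 lists were called lower, 27 of the 33 calls were kept (those of endothelial to mesenchymal transition, complement, coagulation, red blood cells, platelets and alveolar type 2 cells were lost), 0 genes passed and the Tet2 log2 fold change was -0.057. The block moved the medians to 0.55 for TGF-beta and BMP targets, 0.51 for interferon-stimulated genes, 0.32 for coagulation, 0.59 for flow-responsive genes, -0.17 for ribosomal proteins, 0.47 for alveolar type 2 cells and 0.20 for fibroblasts. Genes at an unadjusted p under 0.05 numbered 2982 (1574 higher and 1408 lower) against 1098 (997 and 101) without the block, and the lowest adjusted p was 0.130 against 0.740. With the block the unpaired WT library is fitted exactly, so little residual spread was left to estimate. The paired deviations correlated at 0.22 and 0.49 over 2 pairs, and the samples share only a number. These correlations are not independent, since the deviations of the 2 TET2KO libraries from their mean mirror each other. Scaling on the endothelial list shifted the median of all genes by -0.77. It is given here as counts, since its values per gene and list were left out after many were seen to change sign. Camera called 28 lists higher, neutrophils among them, and 3 lower, class I antigen presentation among them, and edgeR called 0 genes. Camera compares a list with all other genes, so a nearly common shift of the genes leaves its calls nearly unchanged. Higher here means relative to the other genes, and does not show that a list stayed above 0 in TET2KO. With this scaling 6754 genes were at an unadjusted p under 0.05 by edgeR, 21 higher and 6733 lower, and the median of all genes was -0.85. With this scaling the median of the 20 genes with the smallest p was 0.33 against 1.10 before, with 20 above 0 and 1 at an unadjusted p under 0.05. The median of all genes was -0.08 in the edgeR test, 0.06 with library totals, 0.13 on log2(TPM + 1), 0.15 on log2(TPM + 0.1) and 0.08 on unfiltered TPM.

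Tet2 ranged from -0.094 to 0.18 over the left-out libraries, the gene Tet3 from -0.11 to 0.23, the gene Lyz2 from -1.63 to 0.13, the gene Cd74 from -0.70 to 0.17 and the gene Ighm from -0.63 to 0.23, none of them past the threshold. With the replicate block Cd74 was at 0.30 and Ighm at 0.37, and on TPM values the gene Ptprc was at 0.0061 or 0.0063, Cd74 at 0.086 and Ighm at 0.17. The others of the 66 genes followed through the settings kept their direction. Genes named only under the other observations below were not followed.

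Among the 33 called lists the median changed sign in 4 of 495 values: S phase on TPM (0.012), and S phase (-0.35 to 0.11), fatty acid and cholesterol metabolism (-0.52 to 0.14) and platelets (-0.15 to 1.39) over the left-out libraries. Among the 20 uncalled lists it did so in 51 of 297 values, and the cause was not tested. With upper quartile scaling these were hypoxia (0.037), senescence (0.00011), heat shock (0.056) and germline genes (0.046). With library totals they were NF-kappaB (0.069), class I (0.013), hypoxia (0.091), senescence (0.071), heat shock (0.11), DNA methylation (0.013) and germline genes (0.11). Without a filter they were hypoxia (0.0022) and heat shock (0.013), and with the stricter filter neutrophils (-0.28). With the replicate block they were NF-kappaB (0.050), class II (0.24) and B and plasma cells (0.27). On TPM values they were NF-kappaB (0.13), class I (0.093), class II (0.075), inflammasome (0.17), mitochondrially encoded genes (0.064), hypoxia (0.16), G2 and M phase (0.073), p53 targets (0.037), senescence (0.24), unfolded protein response (0.074), heat shock (0.19), DNA methylation (0.083) and B and plasma cells (0.11). Over the left-out libraries the ranges were -0.16 to 0.11 for NF-kappaB, -0.49 to 0.094 for the inflammasome, -0.71 to 0.16 for oxidative stress, -0.40 to 0.0034 for glycolysis, -0.47 to 0.38 for G2 and M phase, -0.23 to 0.036 for p53 targets and -0.12 to 0.61 for senescence. They were -0.32 to 0.15 for the unfolded protein response, -0.17 to 0.072 for heat shock, -0.043 to 0.15 for germline genes, -0.0019 to 0.23 for immediate early genes, -1.40 to 0.18 for macrophages and monocytes, -0.24 to 0.26 for T and NK cells, -0.66 to 0.15 for B and plasma cells and -0.62 to 0.17 for class II.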

Other observations

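Of the tests below, those on gene length and on scaling by the endothelial list were set before their results were seen, and the others only after. The condition on the precision of the endothelial scaling test was also set after. Without that condition its result met what a larger share of endothelial RNA predicts, but a change of transcription shared by the list predicts the same.

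Genes listed in the authors' deposited table as higher, with a log2 fold change over 1, held more endothelial identity genes than independent draws would. They held 5 of the list's 30 members (Cdh5, Plvap, Sox17, Sox7 and Tek) against 0.265 expected (one-sided Fisher's exact test, adjusted p = 0.00038 over the lists and directions). That test treats genes as independent, while the correlation within this list was estimated at 0.568 with the groups of the labels. The arterial list had 4 of 15 (Cxcl12, Gja4, Sema3g and Sox17; adjusted p = 0.00038 by Fisher's exact test) and interferon-stimulated genes had 4 of 44 (Ifit1, Iigp1, Oasl2 and Rtp4; adjusted p = 0.010 by Fisher's exact test). Genes listed as lower in the authors' deposited table held 4 of 23 macrophage and monocyte members (Chil3, Lyz2, Marco and Trem2; adjusted p = 0.00044 by Fisher's exact test). Among the higher genes, the angiogenesis, general capillary and hypoxia lists passed as well (adjusted p = 0.00044, 0.0047 and 0.018 by Fisher's exact test). The aerocyte and lymphatic lists had 0 of 16 and 0 of 10, and the venous list had 1 of 13 higher and 1 of 13 lower. The genes named here were picked by the overlap, and the authors' deposited table sets WT replicates 1 and 2 against the other 3 libraries. Immediate early genes were abundant in all libraries: Fosb, which is induced within minutes by stress or tissue dissociation, stood between 3163 and 5714 CPM before TMM scaling, a gene chosen after its values were seen.

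For the higher level of endothelial genes in the TET2KO libraries, WT replicate 2 alone is not the whole cause, since the list's median was 0.63 without it, and nor is gene length, since the median was 0.76 after a trend on length was removed. A larger share of endothelial RNA in the TET2KO libraries stays open. Once the libraries were scaled on the list, 1 of its 30 members differed at an unadjusted p under 0.05. This was Fli1, named after its value was seen. The median standard error of the members was 0.29, so few such differences could have been seen. The scaling also removes any rise that the members share. A change of transcription shared by them would leave as few members differing, so this test cannot separate it from a larger share. Against a lower share of leukocytes alone, which would raise all other cell types alike, mesothelium lay above fibroblasts (the fibroblast list minus mesothelium was -1.02, SE 0.10). This pair was picked from the 55 pairs below after the values were seen. The mesothelium list also had its highest share of counts in WT replicate 2 (0.0376%). Red blood cell genes were lower (endothelial minus red blood cell list 1.23, SE 0.25, between TET2KO and WT). That list cannot decide the question, since red blood cells, like leukocytes, may enter an isolate with blood. A lower share of leukocytes alone stays open. Of the 55 pairs of 11 non-leukocyte lists, 12 lay over 2 standard errors apart. Several of them were with the red blood cell list, and most of the others with the mesothelium list. Another split of the libraries gave 18. The endothelial list minus the mean of the lists for alveolar type 1 and type 2 cells, airway epithelium, fibroblasts, pericytes and mesothelium was -0.19 (SE 0.40). A change of transcription with TET2 loss, the biological explanation that the design names, was not tested and stays open beside the share of cells.

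The mismatch between the labels and the authors' deposited table was weighed in a pair of tests. DESeq2 with WT replicate 3 among the TET2KO libraries matched the deposited log2 fold changes to within 4.0e-05, and the best of the other 9 splits missed by 5.03, which is what a table computed with that grouping gives. Whether the labels or the table hold the intended group of WT replicate 3 cannot be told apart from these values: its Tet2 level relative to the mean of the TET2KO libraries was -0.20, and relative to that of the other WT libraries -0.26, on the log2 scale, and the ranges of Tet2 in the other WT libraries and in TET2KO overlapped. Other values pointed both ways: the second principal component (21.4% of the variance) placed WT replicate 3 at -25.6, by WT replicates 1 (-25.7) and 2 (-16.6) and apart from TET2KO (15.7 and 52.2), but across genes its highest Pearson correlation was with TET2KO replicate 1 (0.987), against 0.981 with WT replicate 1, 0.971 with TET2KO replicate 2 and 0.944 with WT replicate 2.

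WT replicate 2 stood apart, and many macrophage genes were highest in it. Of the 24 macrophage and monocyte members 16 were highest there, among them Chil3, Lyz2 and Mrc1, while 7 (C1qa, C1qb, C1qc, Cx3cr1, Ccr2, Ly6c2 and Itgam) lay below the mean of the other libraries by more than the SD of these, which argues against an excess of every macrophage and monocyte population. The genes named here were chosen after their values were seen. Which populations brought the higher genes stays open, since the list was not divided by population before its values were seen. Immediate early genes in WT replicate 2 lay only 0.14 above the mean of the other libraries, against 1.68 for the macrophage list. As read from those genes, this goes against a much stronger dissociation response there. It does not exclude such a response, since the libraries also differed in cell content. No biological explanation was tested, since the labels give WT replicate 2 no condition of its own.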
